A study of Trichoderma reesei with 15 samples.

How the data were processed

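Transcript abundance was measured by RNA sequencing in mycelium of Trichoderma reesei, a filamentous fungus used to produce cellulases. Per the labels' protocols, cultures grew for 96 h at 28 °C in a minimal medium that offered cellulose as the carbon source, in constant darkness, RNA was extracted with a plant RNA kit, and stranded libraries were made after depletion of ribosomal RNA. The 15 libraries fell into 5 groups by their titles: the parent strain QM6aΔmus53 in the experiment tagged DD1 (2 libraries) and in the experiment tagged DD3 (2 libraries), the pp2A deletion in DD1 (4 libraries), the pph5 deletion in DD1 (3 libraries) and the pph5-2 deletion in DD3 (4 libraries). The meaning of the tags DD1 and DD3 is not given in the sources used here. Experiment stands below for the libraries that share a tag, and whether these were grown together is not known. Labels conflicted in 2 places: pp2A replicate 1 carries a type label of WT although its title, source name and cell line name the pp2A deletion, and the pph5-2 libraries carry the pph5 strain as source name and cell line although title and type name pph5-2. The titles decided the group in both cases. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

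The deposited table holds unnormalised read counts per gene, 1 column per library, with the gene length. HISAT2 2.2.1 is named in the submitters' processing notes, without its role. The counting settings, their use of strand, the genome build and the annotation are not given in the sources used here, so reads from overlapping or antisense genes, and from near-identical copies, may have been assigned to either gene. The table lists 10879 genes, of which 332 had 0 counts in all libraries. Of the lengths 94.7% are multiples of 3, so lengths are taken here as coding lengths, although the remaining ones do not bear this out. Each count column was matched to its sample through the label that names the column. The deposited counts summed to between 6026511 and 13572121 per library.

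The table holds 10876 systematic identifiers, which it pairs with no gene names, and 3 rows named in another form, with 0 counts in all libraries. Of all these, 0 matched the reference gene table used here, which lists 9116 genes. The gene lists fixed before the data were examined (cellulases, xylanases, regulators and others) and the tests of those lists could therefore not be run, and no cellulase gene is named. Systematic identifiers consist of 1 of 7 letters, a running number and W or C. What letter and number stand for is not given in the sources used here. The rule fixed beforehand for naming genes took those with an adjusted p under 0.05, a mean of at least 10 CPM (counts scaled to a common library size) in the higher group and no overlap between the libraries of both groups, ranked by log2 fold change. It would have named 6 genes per direction. For want of gene names, at most 2 identifiers per direction are printed by this rule for each comparison. A candidate for the deleted gene that fell takes 1 of these places whatever its rank, and candidates are also given elsewhere.

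Differences were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes were kept by filterByExpr over the 5 groups, which left 8912 genes. The genes left out held at most 0.0296% of the counts of any library. Counts were scaled by TMM, and a robust quasi-likelihood model with 1 mean per group was fitted over all 15 libraries, so that groups of 2 libraries shared the estimate of spread. Contrasts gave each deletion against the parent of its own experiment, pp2A against pph5, the difference between the pph5-2 and pph5 responses, and the parents of DD3 against those of DD1. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes under 0.05 were called. Adjusted p-values below come from this test unless another is named. Levels are means ± SD of TMM-scaled CPM, except that candidates for deleted genes are given in CPM of the library total. Principal components and correlations used log2 CPM with a prior count of 2. Sets of genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it, adjusted over 11 sets and 3 comparisons.

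Candidates for the deleted genes were sought by a rule fixed beforehand: a mean of at least 5 CPM in the parent, under 5% of it in the deletion, and no overlap between libraries. A stricter rule was added after seeing the data, with under 1% remaining and at least 5 CPM in each library outside the deletion group. For libraries without a count, the floor was 3 counts over the group, and fold differences are then lower bounds. Intervals and floors cover counting error only, as reads without molecular identifiers are not independent molecules.

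The test was tried on simulated counts drawn from the real means and library sizes, with 200 genes changed. The changed genes had a mean of at least 5 CPM. Counts were drawn independently for each gene and library, so spread that libraries share across genes was left out. Recovery in the real data may therefore be lower. For pp2A against its parent, 42% of 2-fold, 82% of 4-fold and 94% of 8-fold changes were recovered, with 5 false calls among 8786 genes. For pph5 against its parent, these shares were 48%, 84% and 94%, with 9 false calls among 8810 genes. For pph5-2 against its parent, they were 42%, 84% and 90%, with 7 false calls among 8788 genes. The median standard error of a log2 fold change in the real data was 0.24 for pp2A, 0.25 for pph5 and 0.24 for pph5-2.

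Alternatives fixed before the data were examined were median-ratio (RLE) and upper-quartile scaling, DESeq2 1.42.0, other filters on low counts, a fit over only the groups compared, the replicate number as a block, leaving out each library in turn, and a threshold of 2-fold. Alternatives added after seeing the data were scaling by library size only, a surrogate variable from sva 3.50.0, the parents of both experiments as 1 group, counts of genes outside the range of all other libraries, and sets formed by identifier, length and abundance. No pair of libraries agreed within sampling noise, since the lowest chi-square per degree of freedom within a group was 5.28.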

Results

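The study profiled transcripts in a parent strain of Trichoderma reesei and in strains lacking a protein phosphatase, all grown on cellulose in darkness. The parent, QM6aΔmus53, is derived from the strain QM6a and lacks mus53, a gene of non-homologous end joining whose loss favours targeted gene replacement. PP2A and PP5 type enzymes are serine/threonine protein phosphatases, which remove phosphate groups from proteins. The series asks what such phosphatases do in the regulation of cellulases, the enzymes that break down cellulose. Library totals were 9310996 and 9906943 counts for the parent in experiment DD1, 7862390 to 11134647 for Δpp2A (n = 4), 6026511 to 9842288 for Δpph5 (n = 3), 9733138 and 10499078 for the parent in experiment DD3, and 8990198 to 13572121 for Δpph5-2 (n = 4).

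Each deletion strain lacked the transcript of a different gene. TrG1101W (coding length 846 bases) had 0 counts in 3 of the 4 Δpp2A libraries and 4 counts in the other, against 247 and 319 in the DD1 parent. Its level was 29.4 ± 4.01 CPM (SD, n = 2) in the parent and 0.120 ± 0.240 CPM (SD, n = 4) in Δpp2A. The parent mean was 279.6-fold the pooled Δpp2A level, 4 counts over the summed totals of its 4 libraries, with a 95% counting interval of 109 to 1026. TrE1020W (1818 bases) had 0 counts in the 3 Δpph5 libraries and 973 and 1308 counts in the DD1 parent, at least 961-fold lower. TrE0027W (1455 bases) had 0 counts in the 4 Δpph5-2 libraries and 166 and 204 counts in the DD3 parent, at least 267-fold lower.

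These genes are candidates for the deleted ones, since the labels name no identifier. By the rule of under 5% remaining, 28 genes qualified in Δpp2A, 1 in Δpph5 and 2 in Δpph5-2. The stricter rule added after seeing the data left 1 gene per strain. In Δpp2A its limit of under 1% remaining alone left 7 genes, and the demand of at least 5 CPM in each other library left 1. TrE1020W was at 124 ± 10.1 CPM (SD, n = 4) in Δpph5-2, so the libraries labelled pph5-2, whose source name reads pph5, contained the transcript missing from Δpph5. Δpp2A replicate 1, which has a type label of WT, had 0 counts of TrG1101W. Expression of mus53, which the parent lacks as well, was not analysed here.

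**Figure D1:**
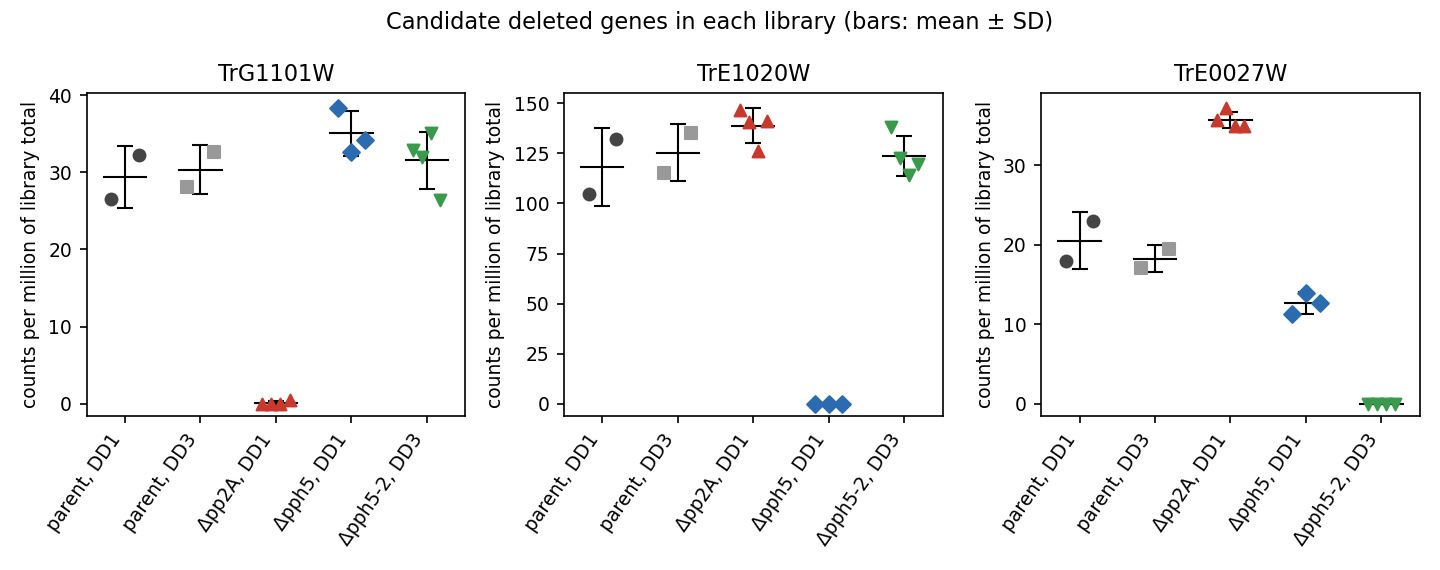
CPM of the library total (vertical axes) for TrG1101W, TrE1020W and TrE0027W in each library, by group, with points for libraries and bars for mean ± SD. Each gene lies at or near 0 in 1 deletion strain, with at most 4 counts, and at 11.3 CPM or more in each library of the other groups.

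The comparison of Δpp2A with its parent asked which transcripts depend on the pp2A gene. Between Δpp2A and the parent 1665 of 8912 genes (18.7%) differed, of which 708 were higher and 957 lower in Δpp2A, and 388 of the higher and 524 of the lower genes differed at least 2-fold. The parent libraries were over 4-fold apart in 9.09% of the lower genes, 0.989% of the higher genes and 6.75% of all genes tested. TrG0789C rose from 1.05 ± 0.48 CPM (SD, n = 2) in the parent to 344 ± 67.3 CPM (SD, n = 4), a log2 fold change of 8.37 (SE 0.62, adjusted p = 8.07e-06 in edgeR's quasi-likelihood test). TrA1907C rose from 1.34 ± 0.83 to 412 ± 79.0 CPM (log2 fold change 8.21, SE 0.86, adjusted p = 1.10e-04 in the same edgeR test). In the Δpph5 and Δpph5-2 libraries neither gene exceeded 2.35 CPM.

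Among the genes that fell and met the naming rule, the most negative fold change was that of TrG0015C (log2 fold change -8.83, SE 2.78, adjusted p = 0.0453 by edgeR). The candidate TrG1101W, named whatever its rank, had a log2 fold change of -8.23 (SE 0.53, adjusted p = 2.10e-06 by edgeR). TrG0015C was at 432 and 7.20 CPM in the parent libraries and at 0.489 ± 0.674 CPM (SD, n = 4) in Δpp2A. Without parent replicate 1 its log2 fold change was -3.91 (adjusted p = 0.509 by edgeR), and with a surrogate variable it was -3.89 (adjusted p = 0.306 by edgeR). It also varied in the other strains, from 1.17 to 375 CPM among the Δpph5 libraries and from 0 to 231 CPM among the Δpph5-2 libraries.

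The transcripts with the highest mean over these libraries took a smaller part of the counts in Δpp2A. Of the 100 genes with the highest mean over all libraries, 34 fell, 2 rose and 64 were not called, with a median log2 fold change of -0.47. These genes held 17.8 ± 0.620% of the counts (SD, n = 4) in Δpp2A and 24.6 ± 0.261% (SD, n = 2) in its parent. The set was lower than other genes by camera (adjusted p = 2.4e-05), but not with the correlation estimated from the data (adjusted p = 0.306 with an estimated correlation). Fry, which tests only whether the set moves on balance one way, gave an adjusted p of 0.00220. With scaling by library size only, the medians of the set and of all genes both moved up, to -0.18 and 0.28. Their difference was -0.46 against -0.45 with TMM, but it could hardly change, since scaling shifts all genes of a library alike. Under that scaling 23 genes of the set were lower. In Δpph5 and Δpph5-2, 0 of the 100 genes were called, and their medians were 0.03 and -0.07. The set was formed after seeing the data, from the same counts that were tested. Its ranking used all 15 libraries, of which 11 are not Δpp2A. Genes lower in Δpp2A were thereby favoured, so a part of the fall may be built in.

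**Figure D2:**
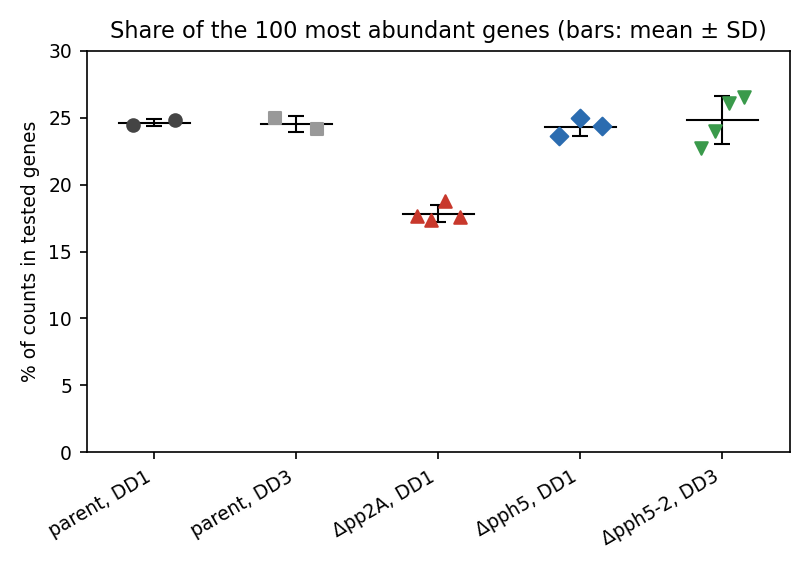
Share of the counts in tested genes (vertical axis, percent) held by the 100 genes with the highest mean over all libraries, by group, with points for libraries and bars for mean ± SD. The 4 Δpp2A libraries lie between 17.4% and 18.7%, below the 22.7% to 26.5% of the Δpph5-2 libraries and the other groups.

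The Δpp2A libraries also stood apart from the parent and both other deletions. In 885 genes all 4 Δpp2A libraries were above, and in 829 genes below, each of the 11 other libraries. If all 15 libraries were interchangeable, chance would give 6.53 genes each way (0.0733%). They were not, since 8 of the 11 had their nearest library in another group. Any 4 libraries that are alike could exceed that value, so it does not measure an effect of the strain. Scaling by library size only, added after seeing the data, gave 1824 above and 387 below. Of the 708 genes that rose, 534 (75.4%) lay above all 11 others, and of the 957 that fell, 660 (69.0%) lay below them.

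The number of calls depended on single libraries, and it rose to 2337 without Δpph5 replicate 1, which is not part of the comparison. It was 890 without parent replicate 1, and 1105 and 1108 without Δpp2A replicates 1 and 4, and 3029 with the parents of both experiments as 1 group. Scaling by library size only, added after seeing the data, moved the median of all genes by 0.30 on the log2 scale and gave 1401 higher and 510 lower genes.

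The comparison of Δpph5 with its parent asked the same of pph5. Apart from TrE1020W (at least 961-fold lower, adjusted p = 8.19e-11 by edgeR), 0 genes passed the threshold, and the gene next in rank had an adjusted p of 0.0615. Without Δpph5 replicate 2, 6 genes were called, 5 of them higher, and without parent replicate 2, 4 genes were called, all lower. An unadjusted p under 0.05 was reached by 573 genes, where 445.6 are given by chance, and by 1950 without parent replicate 1 and 1322 without Δpph5 replicate 1. The candidate of the other strain, TrE0027W, was at 12.6 ± 1.33 CPM (SD, n = 3) in Δpph5 and 20.5 ± 3.59 CPM (SD, n = 2) in the parent, which was not called (log2 fold change -0.64, SE 0.19, adjusted p = 0.610 by edgeR). DESeq2 called 25 genes, 14 higher and 11 lower. With only the 5 libraries of this comparison in the fit, TrE1020W was not called (adjusted p = 0.354 by edgeR). Its mean in that fit was still 0 CPM in Δpph5 and 117 CPM in the parent.

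Pairs of Δpph5 libraries correlated across genes at 0.898 to 0.976, and 173 to 758 genes differed over 4-fold within a pair. Δpph5 and DD1 parent libraries correlated over a like range, from 0.894 to 0.976. The 2 parent libraries of DD1 correlated at 0.901, with 713 genes over 4-fold apart. Δpph5 replicate 2 was closest to parent replicate 1 (r = 0.976 across genes, which are not independent replicates), and Δpph5 replicate 1 was closest to a Δpph5-2 library (r = 0.975).

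The comparison of Δpph5-2 with the DD3 parent gave a similar count. TrE0027W fell at least 267-fold (adjusted p = 8.30e-07 by edgeR), and 0 other genes passed. Without DD1 parent replicate 1 or 2, 5 genes were called each time, and without Δpph5 replicate 1, 6 genes, although these libraries are not part of the comparison. The gene next in rank had an adjusted p of 0.0708, and 770 genes had an unadjusted p under 0.05 against 445.6 by chance, and 507 and 455 without DD3 parent replicates 1 and 2. DESeq2 called 79 genes, 60 higher and 19 lower. With only the 6 libraries of this comparison in the fit, TrE0027W was not called (adjusted p = 0.0873 by edgeR). Its mean in that fit was still 0 CPM in Δpph5-2 and 18.9 CPM in the parent. The single call of that fit was TrF1049W (log2 fold change -2.78, SE 0.20, adjusted p = 0.0378 by edgeR), named after its values were seen.

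**Figure D3:**
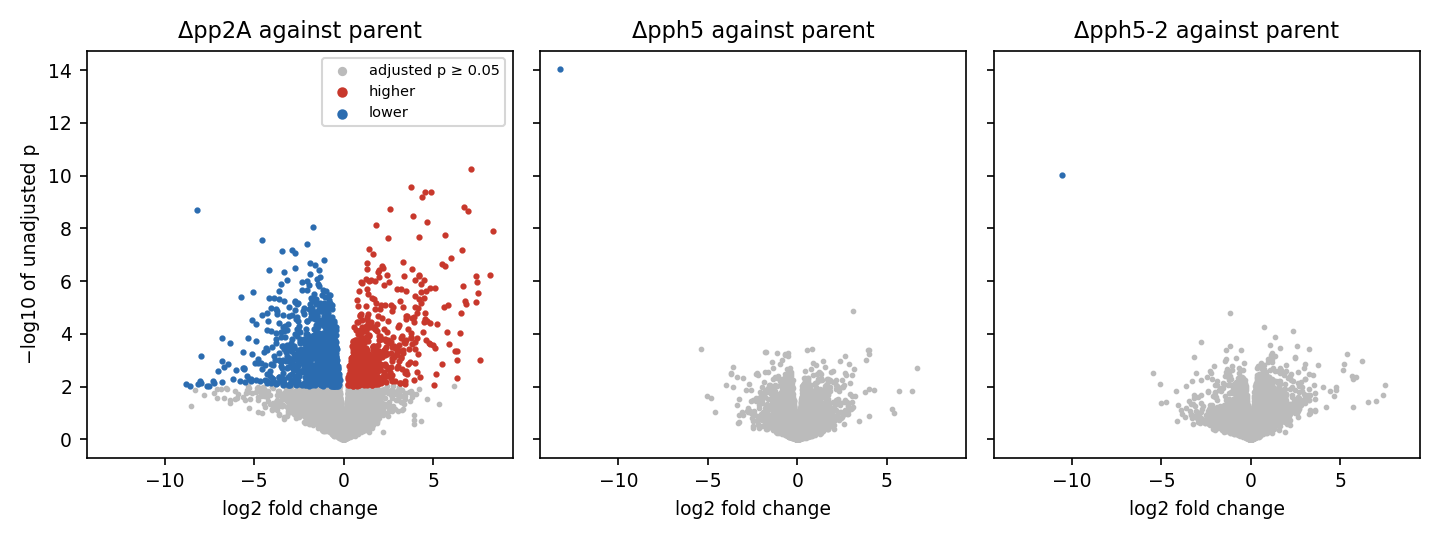
Log2 fold change (horizontal axes) against −log10 of the unadjusted p from edgeR (vertical axes) for the 8912 genes tested in each deletion against its parent. Red points (708 in Δpp2A) were called higher and blue points lower, and the single blue points in Δpph5 and Δpph5-2 are TrE1020W and TrE0027W, whose fitted positions depend on the prior count.

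Whether Δpph5-2 responded differently from Δpph5 was tested as a difference of the responses. The 2 genes that passed were the candidates themselves, TrE1020W (adjusted p = 7.84e-10) and TrE0027W (adjusted p = 1.04e-05), both by edgeR's quasi-likelihood test. No size is given for either, since each had 0 counts in 1 of the groups. An unadjusted p under 0.05 was reached by 298 genes, where chance gives 445.6, but by 1572 without parent DD1 replicate 1 and by 1483 without Δpph5 replicate 1. DESeq2 called 2 genes. The median standard error of a log2 difference was 0.35.

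Δpp2A and Δpph5, which share the tag DD1, were compared directly. In Δpp2A 1261 genes were higher and 1751 lower than in Δpph5, 3012 of 8912 genes (33.8%), and 1492 of these differed at least 2-fold. Of the genes that rose in Δpp2A against its parent, 575 were also higher than in Δpph5, and of those that fell, 794 were also lower. Both comparisons use the same Δpp2A libraries, so a part of this overlap is built in. TrG0789C had a total of 2 counts in the 3 Δpph5 libraries and 3440 to 3941 counts per library in Δpp2A (adjusted p = 4.39e-07 by edgeR), a ratio of 4785 in CPM of the library totals with a 95% counting interval of 1325 to 39515. The candidates TrE1020W, with 0 counts in Δpph5, and TrG1101W (log2 fold change -8.52) also passed the threshold. TrE0027W was at 35.7 ± 1.05 CPM (SD, n = 4) in Δpp2A against 12.6 ± 1.33 CPM (SD, n = 3) in Δpph5 (log2 fold change 1.14, SE 0.16, adjusted p = 0.00129 by edgeR). It was named after its values were seen, and it was not called between Δpp2A and the parent (log2 fold change 0.50, SE 0.18, adjusted p = 0.0850 by edgeR), except under upper-quartile scaling (adjusted p = 0.0452) and with library size only (adjusted p = 0.0128).

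By the naming rule, the most negative fitted fold change of Δpp2A against Δpph5 was that of TrF0062W (adjusted p = 0.0177 by edgeR), at 69.3 ± 81.4 CPM (SD, n = 3) in Δpph5 and 0.0736 ± 0.0510 CPM (SD, n = 4) in Δpp2A. With 3 counts in the 4 Δpp2A libraries the ratio was 721 in CPM of the library totals, with a 95% counting interval of 247 to 3495 that leaves out the spread among the Δpph5 libraries. It had between 0.389 and 159 CPM among the Δpph5 libraries, and the call was lost without Δpph5 replicate 2 (adjusted p = 0.0594 by edgeR) and without Δpp2A replicate 1 (adjusted p = 0.0502). With a surrogate variable the fitted log2 fold change, which depends on the prior count, was -1.11 instead of -9.71 (adjusted p = 0.446 by edgeR). The number of calls was 1543 and 1545 without Δpph5 replicates 2 and 3, but 4250 without Δpph5 replicate 1. It was 1942, 1975, 2421 and 1987 without Δpp2A replicates 1, 2, 3 and 4. Scaling by library size only gave 2626 higher and 937 lower genes.

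The Δpph5 and Δpph5-2 responses held 1 called gene each, the candidate of the strain itself, so responses were compared by fold changes and not by shared calls. The fold changes of Δpp2A and Δpph5-2, which have different parent libraries, correlated across genes at r = 0.461 (Spearman's rho 0.473, covariance 0.405), against r = 0.0245 and a covariance of 0.00776 in simulated unchanged groups. The simulation took the DD1 and DD3 parents as independent, while same-numbered parents of both experiments correlated at 0.972 and 0.985, so it leaves that likeness out. Without parent DD3 replicate 1 the correlation was 0.121, without parent DD1 replicate 1 it was 0.197, and with a surrogate variable, added after seeing the data, it was 0.228. The fold changes of Δpp2A and Δpph5, which share the DD1 parent, correlated at 0.103 (rho 0.0542, covariance 0.0785). This was below the r of 0.650 and the covariance of 0.219 that the shared parent alone gives in simulated unchanged groups. Genes changed in Δpp2A widen its fold changes and can lower r, and the simulation leaves out likeness between libraries of different strains. No conclusion is therefore drawn from this difference. For Δpph5 and Δpph5-2 the correlation was 0.217 (rho 0.113, covariance 0.0919). Simulated unchanged groups gave r = 0.0167 and a covariance of 0.00571, again with the parents of both experiments taken as independent.

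The parents with the tags DD1 and DD3 were compared to measure the difference between the tags without a phosphatase deletion. Between DD3 and DD1, 0 genes were called by edgeR and 0 by DESeq2, and 162 genes had an unadjusted p under 0.05, where chance gives 445.6. Without parent DD1 replicate 2, 2 genes were called and 1417 had an unadjusted p under 0.05. Parent libraries of different experiments correlated across genes at 0.972 (replicate 1 of both) and 0.985 (replicate 2 of both) where they had the same number, and at 0.916 and 0.948 where they did not, while the DD1 parents correlated at 0.901 and the DD3 parents at 0.961.

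In the principal components, PC1 held 50.7% and PC2 22.5% of the variance. The 4 Δpp2A libraries lay together, and the parent, Δpph5 and Δpph5-2 libraries were intermixed. Of the 11 libraries other than Δpp2A, 8 had their nearest library in another group.

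**Figure D4:**
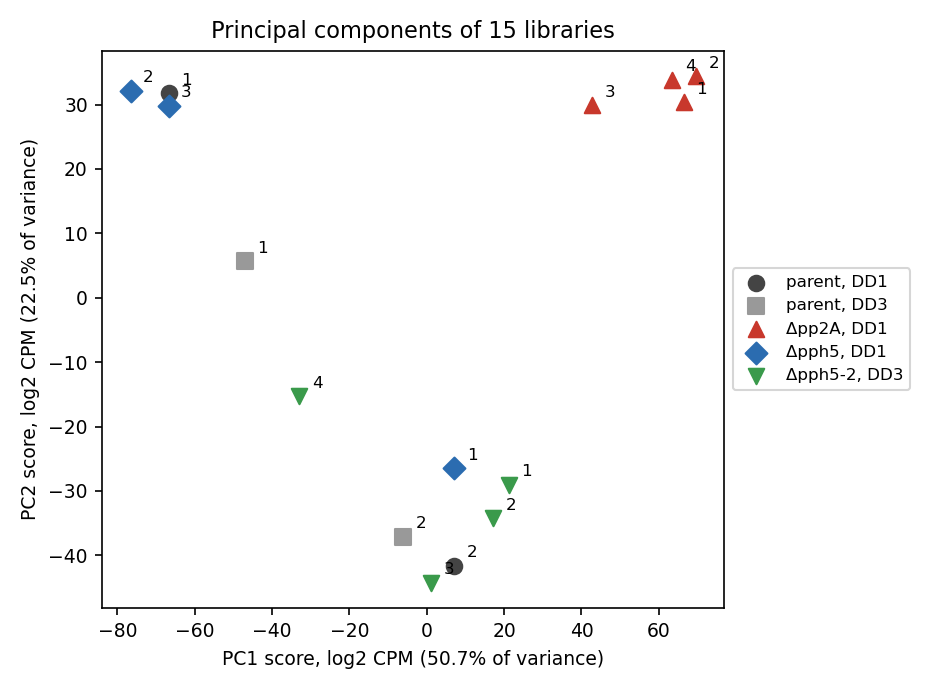
Scores on PC1 (horizontal axis) and PC2 (vertical axis) of log2 CPM for the 15 libraries, with symbols for groups and numbers for replicates. The 4 Δpp2A libraries lie between 42.8 and 69.6 on PC1, and the 2 DD1 parent libraries lie at -66.7 and 7.07.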

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

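The tests of swapped strains, depth, parent spread and neighbouring identifiers, and scaling by library size only, were chosen after the results were seen. Those of the other 2 scalings and of other splits of the libraries were chosen before.

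In Δpp2A the candidate TrG1101W was at 0.418 TMM-scaled CPM in replicate 4, from 4 counts, apart from the 0 counts of the other libraries. In Δpph5-2, replicate 4 lay far from the other replicates for TrF0062W (14.8 CPM) and for TrG0015C (231 CPM). In all, 25 sets of values from Δpp2A and Δpph5-2 were examined for such a distant library, and 3 held one. Chance gives about 1.25 if values are normally distributed, which counts near 0 are not. With all other libraries at 0, as for TrG1101W, any count is flagged. The smaller groups, the parents and Δpph5, were not examined. The responses of Δpph5-2 and Δpph5 differed in TrE0027W (adjusted p = 1.04e-05) and in TrE1020W (adjusted p = 7.84e-10), each by edgeR's test of the difference and each the candidate for the deleted gene of 1 strain.

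Libraries of the same strain differed widely: the DD1 parents had 713 genes over 4-fold apart, and Δpph5 pairs up to 758. Swapped or mislabelled deletion strains are argued against by genes found at 2 levels without use of the labels. Of 3 such genes low in the minority of libraries, each was low in exactly the libraries of 1 deletion strain. They are the candidates already picked with the labels, so this outcome was known before the test. The limit to the minority, set afterwards, left out TrG0638W, which was low in 11 libraries and cut across strains. Sequencing depth is argued against as the whole cause, since the DD1 parents had these 713 genes at a depth ratio of 1.06 and the Δpp2A pair of most unequal depth (1.42) had 36, although the Δpph5 pair with the most, 758, was also the most unequal (1.63). A difference in culture state, such as growth or sampling, may remain as a candidate explanation, but no label records one and no test of it was run, and neither was a swap between parent libraries.

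Many genes differed between Δpp2A and its parent. Of the 1665 called genes, 71.7% lay outside the range of all 11 other libraries, not of the 2 parent libraries alone. This argues only in part against the parent spread as the whole cause. The same Δpp2A libraries, and the spread among all libraries, made the calls, so a part of that share is built in. The share does not tell an effect of the strain from another likeness among the Δpp2A libraries. The parents were over 4-fold apart more often among the lower genes (9.09%) than among the higher (0.989%), so a part of the lower calls may rest on that spread. Scaling is argued against as the whole cause, since at least 1439 genes were called under 3 other scalings. Of the 1665 calls, 1658 were shared with RLE, 1365 with upper-quartile scaling and 1218 with library size only. With library size only 73.3% of the calls were higher, against 42.5% with TMM, so the balance of directions depended on scaling. A response to loss of pp2A is a hypothesis for the genes outside the range, in which a separate culture state of the Δpp2A libraries could also take part and was not tested.

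For Δpp2A against Δpph5, chance was examined by the other splits of the 7 libraries into 4 and 3. Of the 35 splits, only 1, the real one, called as many as 3012 genes, and the highest of the others called 254. That other split put Δpp2A replicate 3 with the Δpph5 libraries. Mixed splits place the difference between the strains within groups and so widen the spread. Their low counts therefore do not show what chance gives, and only the rank of the real split, 1 of 35, bears on it. Chance cannot be excluded by so few splits. The test also takes the 7 libraries as independent, although no label says that they came from separate cultures.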

How the results depend on the processing

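Scaling by library size, the surrogate variable, pooled parents, range counts and abundance sets were chosen after seeing the data. For pp2A against its parent, the count of calls stayed within 1.5 times 1665 under 3 other scalings (1439 to 1911), 2 other filters, a surrogate variable (1964), DESeq2 (2283) and a fit of its own groups (1536). A threshold of 2-fold gave 912 for pp2A and 1492 for pp2A against pph5. The replicate block gave 298 for pp2A (162 higher, 136 lower), 572 for pp2A against pph5, 8 for pph5-2 and 6 for the difference of responses, and changed no other count of calls. Same-numbered libraries deviated with correlations from -0.725 to 0.242 in 9 pairs, 4 of them over 0.1. Of 15 libraries, 2 matched their own number best. No pairing by number was therefore seen within an experiment, but it is not excluded. The 2 libraries of a parent deviate as mirror images of each other, so their pairs are not independent. Under the block TrF0062W (adjusted p = 0.164 by edgeR) and TrG0015C (log2 fold change -11.28, adjusted p = 0.233 by edgeR) were not called. With a surrogate variable the counts were 5 for pph5, 6 for pph5-2 and 1625 for pp2A against pph5. DESeq2 gave 25 for pph5 and 79 for pph5-2. With only its own groups in the fit pph5 had 0 calls, from fewer libraries. With pooled parents the counts were 3029 for pp2A, 4 for pph5 and 3 for pph5-2. At 20% remaining, 161 candidates for deleted genes were found against 31 at 5%.

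Leaving out 1 library in turn gave 890 to 2337 calls for pp2A, 1 to 6 for pph5, 1 to 6 for pph5-2, 1543 to 4250 for pp2A against pph5, 2 to 2 for the difference and 0 to 2 for the parents. For pp2A and pph5-2 each of the 15 libraries was left out, and for the other comparisons only each library of their own groups. A parent group left with 1 library is assumed to vary like the other groups. The median voom log2 fold change of the 100 abundant genes in pph5, -0.0033, ranged from -0.105 to 0.0815 and was positive without parent DD1 replicate 1 (0.0749), pp2A replicate 3 (0.00033) or pph5 replicate 1 (the highest value), with no call in any of these. Genes outside the range of the other libraries numbered 1824 higher and 387 lower with library size only. Of 299 alternatives for named genes and sets, 274 kept direction and side of the threshold, 21 lost it, 1 gained it and 3 reversed. Other than by fewer libraries or the added threshold, the cause was not tested. Tests of the lists fixed beforehand were not run. Depth limits low genes, and the self-test, which changed no genes of low level, recovered 42% of 2-fold changes for pp2A.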

Other observations

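All sets and tests of this part were chosen after the results were seen. Genes changed in Δpp2A lay close together by identifier. Among the called genes, 230 pairs with consecutive numbers changed in the same direction, against a mean of 135 and a highest value of 174 in 1000 shuffled orders. There were 7 runs of at least 4 consecutive genes called in the same direction, 6 of lower and 1 of higher genes, against a mean of 0.915 runs and at most 4 in shuffled orders. The longest run held 6 lower genes, which a shuffled order also reached. Pairs 2 numbers apart numbered 174, against at most 171 in shuffled orders, and at 3 to 20 numbers apart the 111 to 154 pairs stayed below the highest shuffled values.

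Reads shared between adjacent genes may have added to this pattern. Pairs 2 numbers apart whose middle gene was not called the same way numbered 138, above the mean of 122 but below the highest value of 154 in shuffled orders, so shared reads and coordinated change of neighbouring genes cannot be told apart here. What keeps it open is that the counting settings, and what the order of identifiers stands for, are not given in the sources used here.

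Sets by identifier letter and of the first and last 50 numbers of a letter were not called in any of the 3 comparisons with a parent, nor were genes under 300 bases. The 71 genes of at least 6000 bases were called higher in Δpph5-2 by camera (median log2 fold change 0.11, adjusted p = 0.0150), but not with an estimated correlation (adjusted p = 0.943) or by fry (adjusted p = 0.475).

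Of 10 genes below 1 CPM in some libraries and at least 5 CPM, within 4-fold of each other, in all the rest, 6 were high in the 4 Δpp2A libraries alone and 3 were the candidates for the deleted genes. The remaining gene, TrG0638W, was at 11.6 CPM or more in 4 libraries of the parents and Δpph5 and cut across strains. It was named after its values were seen.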
